A study of Mus musculus with 2 samples.

How the data were processed

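Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase places sequencing adapters into DNA that nucleosomes leave open. The cells were mouse CFU-E, erythropoietin-dependent progenitors committed to the red cell lineage, taken as primary cells from adult male C57BL/6J animals. Per the labels, 2 libraries of 50000 cells each were numbered as biological replicates 1 and 2, came from separate biosamples and carried 1 donor identifier. They form 1 group, so the design holds no comparison between conditions. A pair of instrument models is listed for replicate 1, and no model is listed in the labels used here for replicate 2.

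The analysis began at the peak lists. Per the deposited file listing, the authors called peaks on mm10 for each replicate alone and on the pooled reads of both. The aligner, the peak caller, their versions and the handling of Tn5 offsets and duplicate reads are not given in the sources used here. The fold enrichment of a peak is a ratio over the caller's local background, computed by the authors, and each list has its own scale. The p and q values were deposited by the authors as −log10 values. The fold and score of a peak are the authors' own values and were used only to describe and rank peaks within a list, except that −log10 p values of matched records were compared between libraries as described below. IDR, the irreproducible discovery rate, ranks peaks by how well they repeat between 2 peak sets. The authors deposited ranked lists with their IDR, lists thresholded on it (lowest score 540), a conservative thresholded list made from the true replicates, and less strict overlap lists. Per the deposited file listing, the thresholded and overlap lists derive from the alignments and from a further file whose content the listing does not describe, and the ranked lists derive from the alignments alone. An older list of replicated peaks derives from other files. Signal tracks were not used here. Read depth behind each library is unknown from peak lists, so intervals below cover counting error over regions and genes only.

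Records of a list that overlapped or touched were merged into regions. The main list was the series list thresholded on IDR, and the thresholded list of each replicate stood beside it. Positions are 1-based on mm10. The reference was GRCm38.p6 with GENCODE M21, restricted to the assembled chromosomes. A region was classed by its midpoint as promoter (within 1 kb of any annotated transcription start), exon, intron or intergenic. Regions outside the promoter class are called distal. A gene had an accessible promoter when a region overlapped the window of 1 kb to each side of any of its starts, so a long region can count for a promoter while its midpoint lies outside. A gene's domain was the sequence nearest to its starts, up to 100 kb away.

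Regions of a replicate counted as shared when they overlapped a region of the other by at least 1 bp, and 20 random placements of the regions within their chromosomes gave the level of chance. The 19 gene lists held 330 genes, of which 329 were among the 21911 protein-coding genes of the annotation. Ahsp was not analysed here. Accessible promoters of a list were compared with those of all other protein-coding genes by a two-sided Fisher's exact test. The median number of distal regions per gene was compared with 10000 random lists of equal size matched on the length of the domain, by a two-sided permutation test whose smallest p is 0.0002. Adjusted p values follow Benjamini and Hochberg over the 19 lists, with a threshold of 0.05. Intervals of shares are Clopper-Pearson for gene lists, deciles and small groups, and Wilson for region classes, replicate overlap and motif shares over all summits, at 95%.

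Consensus matches on either strand were counted within 100 bp of a region's strongest summit. Control windows of the same width lay 1 kb to each side and overlapped no region. The 16 consensus sequences were GATA (WGATAR), a pair of CTG and WGATAR separated by 7, 8 or 9 bases, KLF (CCMCRCCC), CTCF (CCASYAGRKGGC), ETS (ACCGGAAGT), PU.1 (RAGGAAGT), NFE2 (TGCTGASTCA), AP1 (TGASTCA), RUNX (TGYGGTY), CEBP (TTGCRCAAY), NRF1 (GCGCATGCGC), NFY (CCAATSR), STAT5 (TTCYNRGAA), EBF (TCCCNNGGGA), HNF1 (GTTAATNATTAAC) and RFX (GTTGCCATGGCAAC). Shares were compared by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the motifs, separately for promoter and distal summits. A consensus match is not a measurement of binding, and summits in 1 set of libraries are not independent replicates.

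The ranked list made from the true replicates holds the records of the compared libraries. The one made from pseudoreplicates was taken to hold those of a random split of the pooled reads into parts of equal size. That the split was random and equal is an assumption, which peak lists cannot check. In the list from the true replicates, 76.5% of records were identical to replicate 1's own in the first set and 73.0% to replicate 2's in the second. The spread of the log2 ratio of −log10 p values was compared between the 2 pairs at 7291 regions with 1 record and a −log10 p of at least 10 in each. Its interval came from 1000 bootstrap draws over chromosomes. The libraries differed by less than the splits did, so it was left open whether they are independent. They were counted as 1 sample, with no SD over replicates and with both libraries' values given.

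The lists of genes, the consensus sequences, the rule for named genes and the tests, apart from those named as later below, were fixed before the data were examined. The rule took the 3 members with the strongest promoter region in each list of the erythroid, cell cycle and progenitor kind (the ribosomal list was treated alike), up to 5 members with a promoter region in each list of another cell type, up to 5 members without one in each erythroid list in alphabetical order, the 10 strongest distal regions, the 10 genes with the most distal regions, and 14 loci with their strongest regions. Some genes that the rule takes are not reported here. Alternatives covered the authors' lists, each replicate alone, promoter windows of 500 bp and 2.5 kb, domains of 50 kb and 500 kb, motif windows of 50 bp, controls at 5 kb or shuffled with dinucleotides kept, overlap of at least 50%, and another gene background. Matching on promoter CpG content (500 bp to each side of the start, 10000 random lists) was added after the data were seen, as were the runs of peak numbers and of motifs by rank on each replicate alone. The comparison of the libraries with random splits of their pooled reads was not among the tests fixed in advance either.

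Copies of strong distal regions were searched with BLAST 2.17.0 at an e-value of 1e-05, with at least 90% identity over at least 100 bp. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, with the random seed 20240. The procedures were tested on simulated data. The promoter test recovered 59 of 60 lists with planted enrichment and called 1 of 320 lists without it, the distal test recovered 20 of 20 and called 0 of 170, and the motif test recovered 8 of 10 and called 0 of 70. Simulated promoters opened independently of each other and of CpG content. Simulated distal regions lay at random, with extra ones beside every gene of the planted lists, and simulated windows were random sequence. These settings are simpler than the data, so they do not give its error rates.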

Results

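ATAC-seq peak lists of mouse CFU-E cells were examined for 1 group of 2 libraries, numbered as biological replicates 1 and 2. The series list thresholded on IDR held 50003 records, which merged into 24394 accessible regions with a median width of 591 bp. The regions covered 16.2 Mb, or 0.613% of the assembled chromosomes. Replicate 1 alone gave 37362 records in 18685 regions covering 12.6 Mb, and replicate 2 alone gave 34239 records in 17854 regions covering 11.4 Mb. The median fold enrichment of the unmerged records over local background, as the authors computed it, was 5.05 in the series list, 5.82 in replicate 1 and 5.96 in replicate 2. The 2 libraries differed by less than random splits of their pooled reads did (given with the replicate comparison below). Whether they are independent could not be told, so they were counted as 1 sample. Values therefore have no SD over replicates, and p values describe genes, regions and windows within this sample.

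The first comparison asked which genes had an accessible promoter. All 28 erythroid transcription regulators, all 13 haem synthesis genes and all 11 genes of late organelle clearance had a promoter region, against 45.8% of all protein-coding genes (10037 of 21911). Among the regulators, the strongest promoter regions were at Kdm1a, a histone demethylase recruited by erythroid repressors (chr4:136602415-136603169, fold 12.3), at Nfia, which favours the erythroid over the granulocytic fate (chr4:97771836-97772647, fold 11.5), and at Rcor1, the corepressor that binds Kdm1a (chr12:111038743-111039452, fold 10.98). In the haem group, strong promoter regions were at Cpox (chr16:58669783-58670560, fold 10.5) and Uros (fold 9.16), which encode enzymes of the pathway. Organelle clearance was led by the mitophagy receptor Bnip3l (fold 12.4) and by Becn1 (fold 11.8) and Gabarapl2 (fold 11.3), which act in autophagosome formation.

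Membrane and surface genes had a promoter region in 23 of 26 cases (88.5%, exact 95% interval 69.8 to 97.6), led by Epb42 (fold 12.5) and Sptb (fold 10.01), which build the red cell membrane skeleton. Iron genes had one in 10 of 11 cases (90.9%, 58.7 to 99.8), led by the haem exporter Flvcr1 (chr1:191025966-191026809, fold 14.9) and the iron-responsive regulators Ireb2 (fold 13.02) and Aco1 (fold 10.7). The member without one in the series list was Hmox1, which breaks haem down. It had one in the conservative list and in the overlap list (fold 5.34 in the latter). Cell cycle genes had one in 25 of 26 cases (96.2%, 80.4 to 99.9), led by the helicase subunit Mcm3 (fold 15.8), thymidylate synthase Tyms (fold 13.5) and the mitotic kinase Cdk1 (fold 12.7). Ribosomal protein genes had one in 20 of 20 cases, led by Rpl11 (chr4:136052740-136053816, fold 16.2), Rpl13 (fold 15.2) and Rplp0 (fold 15.1). These 7 lists exceeded other protein-coding genes by Fisher's exact test, with adjusted p values between 6.0e-09 for the transcription regulators and 0.0060 for the iron genes.

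Globin genes had an accessible promoter in 6 of 10 cases, which did not differ from other genes (60.0%, exact 95% interval 26.2 to 87.8, adjusted exact p = 0.528). The adult beta-globin genes Hbb-bt (fold 6.198) and Hbb-bs (fold 5.81) and the adult alpha-globin gene Hba-a2 (fold 5.08) led this list. The embryonic genes Hba-x, Hbb-bh1 and Hbb-y, and Hbb-bh2, had no promoter region in the series list. Hba-a1 with Hba-a2 and Hbb-bs with Hbb-bt are near-identical copies, so the share of reads assigned to each is uncertain. Erythropoietin signalling genes had a promoter region in 9 of 15 cases (adjusted exact p = 0.336), led by the survival gene Bcl2l1 (fold 10.4), Erfe, whose hormone product lowers hepcidin (fold 9.91), and the signalling inhibitor Spry1 (fold 9.26). Of the 6 without one, the first 5 in alphabetical order were Gab1, Id1, Lyn, Podxl and Socs2. In the less strict overlap list 14 of the 15 had one (adjusted exact p = 0.0018), all but Podxl. The membrane genes without one were Cd36, Kit, which encodes the stem cell factor receptor, and Slc2a1, which encodes a glucose transporter. Replicate 1 alone had a Cd36 promoter region, of fold 5.95. The overlap list of the series held a promoter region at Cd36 (fold 6.14) and at Hbb-bh2 (fold 4.47).

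Genes of most other lineages had an accessible promoter less often than other protein-coding genes. None of 18 hepatocyte genes (upper exact limit 18.5%, adjusted exact p = 6.4e-05) and none of 14 mast cell, basophil and eosinophil genes (upper limit 23.2%, adjusted exact p = 0.00043) had one. The T and NK cell list had 1 of 22 (adjusted exact p = 0.00011), the tyrosine kinase gene Lck (fold 8.99). The B cell list had 1 of 15 (adjusted exact p = 0.0047), the surrogate light chain gene Vpreb1 (fold 11.6). Endothelium and stroma had 1 of 13 (adjusted exact p = 0.0070), the collagen gene Col1a1 (fold 8.71). The macrophage list had 1 of 12 (adjusted exact p = 0.011), the haemoglobin scavenger receptor gene Cd163 (fold 11.04), whose promoter region was in replicate 1's own list (fold 10.9) and not in replicate 2's. The granulocyte and monocyte list had 2 of 21 (adjusted exact p = 0.0012), the protease genes Mmp9 (fold 4.55) and Prtn3 (fold 4.12). The neuron list had 2 of 15 (adjusted exact p = 0.021), Nrgn (fold 9.62) and Rbfox3 (fold 4.06). Stem and early progenitor genes had 5 of 23 (21.7%, 7.46 to 43.7, adjusted exact p = 0.025), among them Runx1 (fold 8.83) and Hlf (fold 6.96). On either replicate's own list they had 2 of 23 (8.70%). Megakaryocyte and platelet genes had 5 of 16 (31.3%, 11.02 to 58.7), which did not differ from other genes (adjusted exact p = 0.336). These were the platelet adhesion receptor gene Gp1ba (fold 10.03), the integrin gene Itga2b (fold 8.94), Vwf (fold 7.45), Rab27b (fold 6.98) and Gp9 (fold 3.30). The promoter regions of Hlf, Mmp9, Prtn3, Rbfox3 and Gp9 were in the series list and in neither replicate's own list. With promoter windows of 500 bp the macrophage list had 0 of 12, so Cd163 counted only with the wider window. The granulocyte and monocyte list then had 1 of 21 and the megakaryocyte list 4 of 16, and all 19 lists kept their side of the threshold. In a comparison with genes matched on promoter CpG content, added after the data were seen, 8 lists lay above and 3 below. The stem (adjusted permutation p = 0.0066), T and NK (0.035) and neuron (0.035) lists stayed below, the globins came to lie above (adjusted permutation p = 0.0023), and the granulocyte (0.130), macrophage (0.722), mast cell (0.512), B cell (0.193), endothelial (0.114) and hepatocyte (0.158) lists no longer differed. The matched genes were drawn singly, whereas the globin genes lie in a beta and an alpha cluster. With the upper 50% of regions by fold the erythroid regulators had a promoter region in 28.6% against 37.4% of other genes (adjusted exact p = 0.491) and the globins in 0% (adjusted exact p = 0.029).

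**Figure D1:**
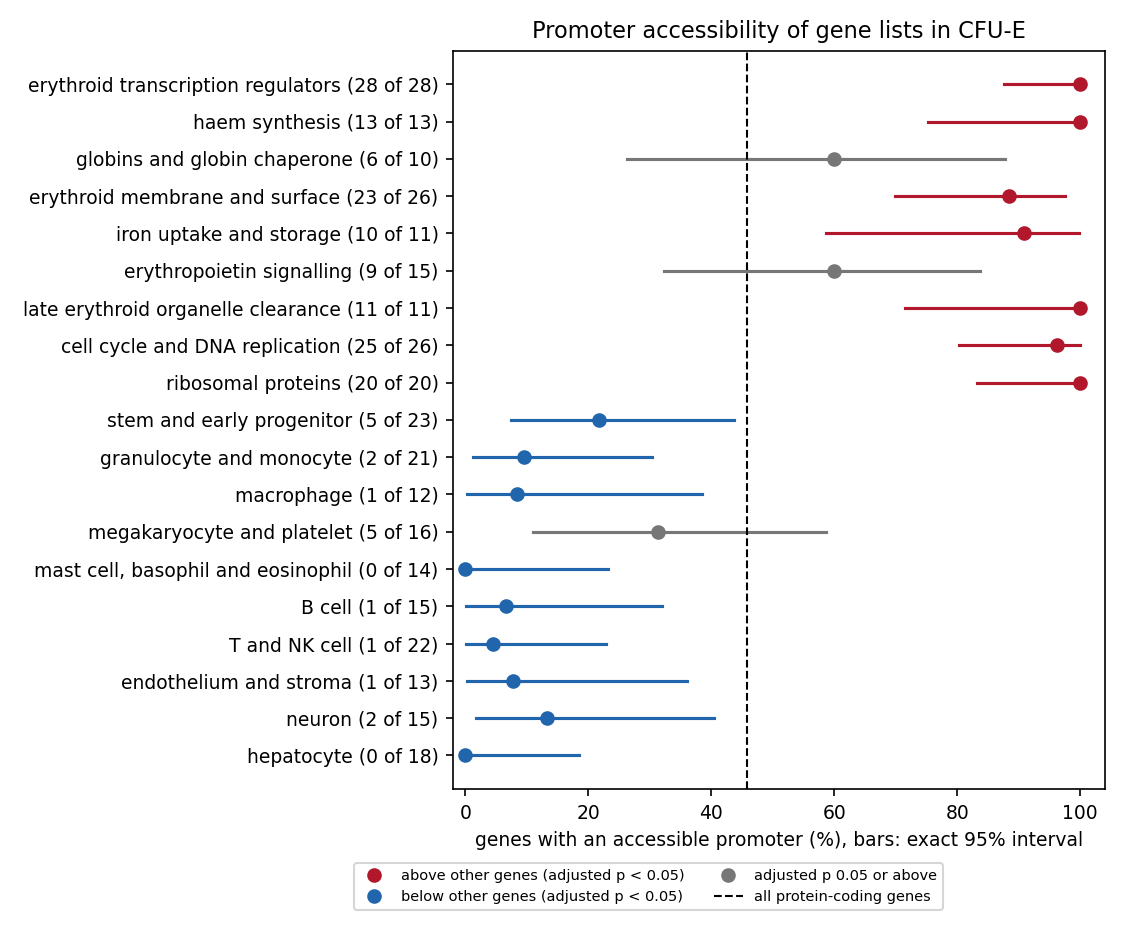
Share of genes with an accessible promoter (%) for each of the 19 gene lists, with exact 95% intervals as bars and the share over all protein-coding genes (45.8%) as a dashed line. The 7 lists in red lie above other genes, the 9 in blue lie below them, and the 3 in grey did not differ.

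The next comparison counted distal regions in the domain around each gene. Erythroid transcription regulators had the most, with a median of 4 per gene, followed by membrane and surface genes with 3, haem synthesis and erythropoietin signalling genes with 2 each, and globins with 1. In the same order, the medians on replicate 1's list alone were 3, 3, 1, 1 and 0.5. On replicate 2's they were 3, 3, 2, 1 and 1. The median over random lists matched on domain length was 0 in each case. The permutation test gave adjusted p values of 0.0019 for the regulators and the membrane genes, 0.0025 for haem synthesis and 0.0046 for globins and for erythropoietin signalling. The globin genes lie in a beta and an alpha cluster, and the test drew its random genes singly. Its p value for globins therefore treats neighbouring genes as independent. The cell cycle list had a median of 0.5 (adjusted permutation p = 0.012), and its median was 0 in the list of either replicate alone. Iron genes (median 1, adjusted permutation p = 0.291) and organelle clearance genes (median 1, adjusted permutation p = 0.209) did not differ from matched lists in the series list. On single replicates' lists the clearance genes did (adjusted permutation p = 0.046 in replicate 1 and 0.032 in replicate 2), as did the iron genes in replicate 2's (0.046), and by the mean the clearance genes did too (0.0092). The ribosomal, stem cell and other lineage lists had a median of 0. Over all their genes, the hepatocyte list had 3 distal regions and the B cell list 0, but a median of 0 in the matched lists left no room to measure a deficit. With the overlap list of the series 2 lists, the regulators and the membrane genes, lay above matched lists, and with the upper 50% by fold 1 did, the regulators. Erythropoietin signalling also lost its call with the conservative list (adjusted permutation p = 0.204) and with domains of 50 kb (adjusted permutation p = 0.171).

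Single genes with the most distal regions were Gse1 with 24, Pde4d and Plcl2 with 16 each, and Elmsan1, Itpr2 and Zfpm1 with 15 each. Zfpm1 encodes a cofactor of GATA1, Pde4d a cyclic AMP phosphodiesterase and Itpr2 a calcium release channel. They were followed by the surface glycoprotein gene Cd24a and the lipid transfer gene Pitpnc1 with 14 each, and by the membrane scramblase gene Ano6 and Dpf3 with 13 each. Sox6, a regulator of globin genes, also had 13. Relative to the length of its domain, Elmsan1 had 14.97 distal regions per 100 kb, Cd24a 11.6 and Zfpm1 9.06, whereas Pde4d, with a domain of 1565 kb, had 1.02.

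At the chosen erythroid loci, the strongest regions by fold often lay outside the promoter. By −log10 p a distal region also led at Alas2 (140), Gata1 (135), Zfpm1 (123), Tal1 (102) and Slc4a1 (129). Except at Slc4a1, it was another region than the strongest by fold. At Tfrc the promoter led by −log10 p, with 163 against 124 for the upstream region. Strength below is by fold. Alas2, which encodes the first enzyme of haem synthesis in red cells, had 5 regions. The strongest were intronic (chrX:150564526-150565274, fold 14.5, and chrX:150549439-150550078, fold 11.3) or 31.0 kb from the nearest start (chrX:150515882-150516852, fold 13.04), and its promoter region had a fold of 4.79. Tfrc, the transferrin receptor gene, had 4 regions, the strongest being 10.8 kb upstream (chr16:32597838-32598416, fold 14.3) and at the promoter (chr16:32608610-32609153, fold 8.55). Gata1, the main erythroid GATA factor gene, had 4 regions, with the strongest 15.1 kb from its nearest start (chrX:7992556-7993869, fold 11.6), the next in an intron (chrX:7970996-7971855, fold 9.83) and promoter regions of fold 6.43 and 4.01. Zfpm1 had 17 regions, 15 of them distal, the strongest being intronic (chr8:122294014-122294667, fold 7.26). Tal1 had 5 regions, with folds of 9.30 (chr4:115038312-115038557) and 8.94 (chr4:115047610-115048606) at the strongest. Klf1 had 3 (chr8:84900856-84901466, fold 6.98, at the promoter), Epor, the erythropoietin receptor gene, had 2, both at promoters (chr9:21962302-21963246, fold 9.36), and Slc4a1, the anion exchanger gene of red cells, had 8 (chr11:102375147-102376364, fold 6.03).

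The beta-globin cluster held 8 regions, 6 of them distal, and the strongest lay 6.01 kb (chr7:103858915-103859534, fold 8.01) and 12.7 kb (chr7:103865543-103866258, fold 6.59) from Hbb-y, ahead of the Hbb-bt promoter (chr7:103813279-103814164, fold 6.198). The alpha-globin cluster also held 8, of which 4 were distal. By fold it was led by chr11:32320895-32321701 (fold 7.87), the Hba-a2 promoter (chr11:32296041-32297615, fold 5.08) and the Hba-a1 promoter (chr11:32283215-32284889, fold 4.37). By −log10 p the promoters of Hba-a2 (111) and Hba-a1 (94.9) stood above chr11:32320895-32321701 (43.8). Only regions nearest to a globin gene's start were counted, so regions nearest to neighbouring genes are left out. Runx1, a regulator of blood stem cells and megakaryocytes, had 11 regions, with the strongest in an intron (chr16:92801460-92802260, fold 11.2). Spi1, which encodes PU.1 and drives myeloid and lymphoid fates, had 1 intronic region (chr2:91101463-91101904, fold 6.80), absent from replicate 2's own list. No region was in the domains of Gata2, a GATA factor of earlier progenitors, or Kit. The less strict overlap list held 3 regions at Gata2, the strongest of fold 4.15 (chr6:88198475-88198756, promoter), and 1 at Kit of fold 4.78 (chr5:75624215-75624661, intron).

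**Figure D2:**
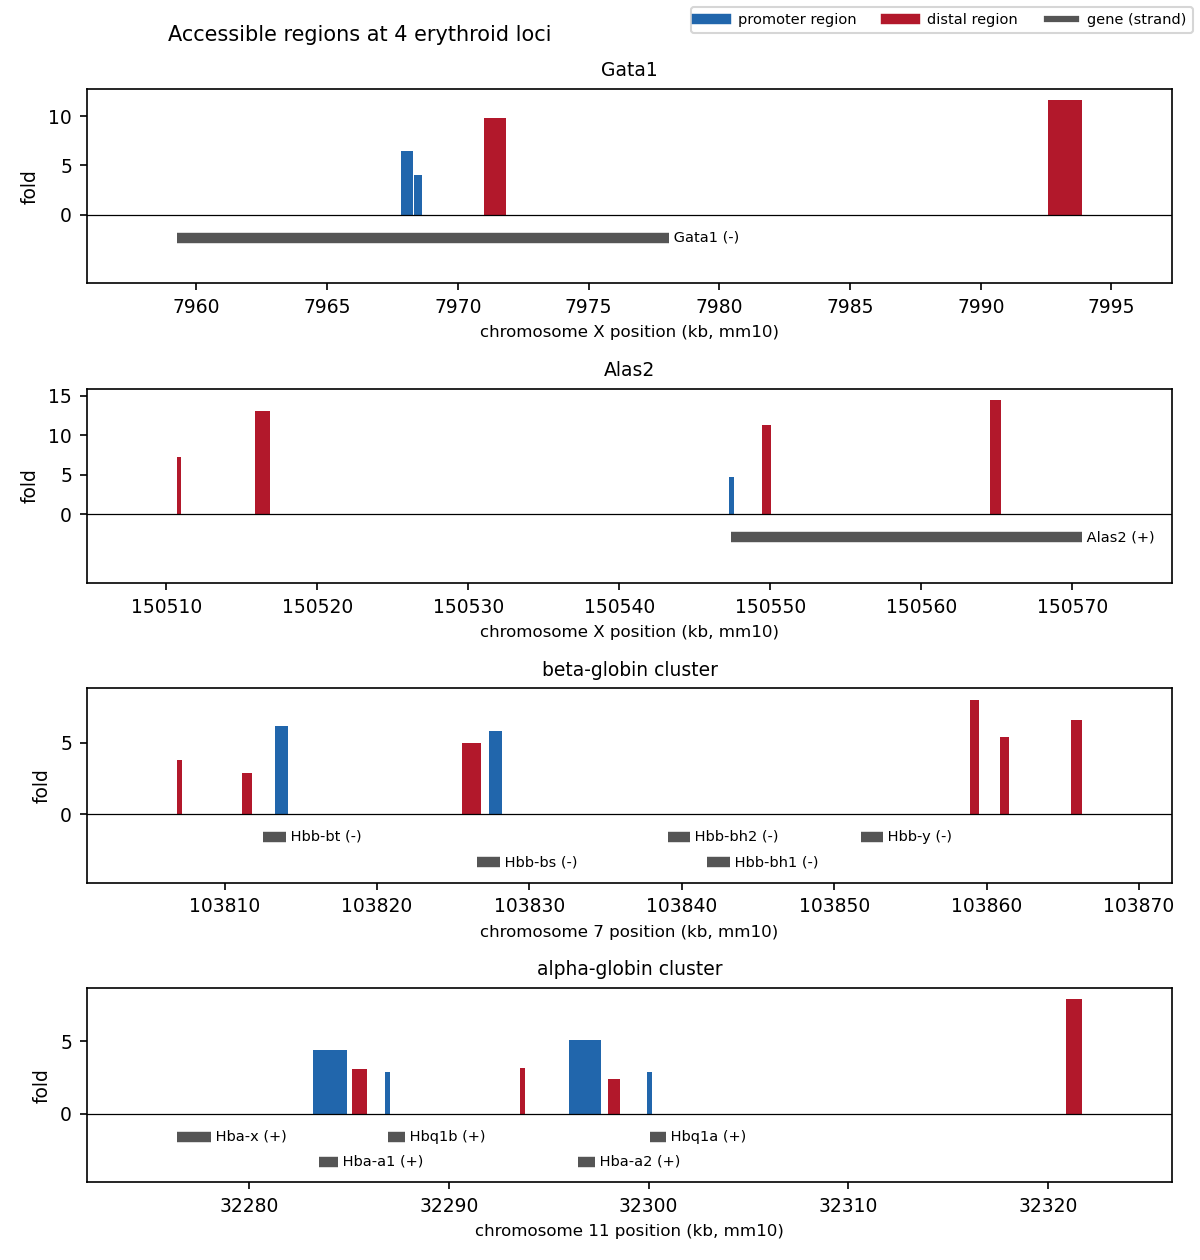
Accessible regions around Gata1, Alas2 and the beta-globin and alpha-globin clusters, with position in kb (mm10) on the horizontal axis, the authors' fold enrichment of each region as bar height (promoter regions blue, distal regions red) and genes as grey bars. At Alas2, distal regions of fold 14.5 and 13.04 stand above the promoter region of fold 4.79.

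Consensus matches were then compared between summits and flanking windows. At 12039 distal summits, GATA was matched at 49.8% (95% interval 48.9 to 50.7) against 29.2% of 21976 flanking windows, an odds ratio of 2.40 (adjusted exact p = 1.7e-306). The pair of CTG and GATA, a composite recognised by TAL1 and GATA1 complexes, was matched at 15.8% against 2.03% (odds ratio 9.03), and KLF, the CACCC-type site of KLF1 and of other KLF and SP factors, at 18.97% against 7.06% (odds ratio 3.08, adjusted exact p = 2.2e-229). CTCF, the insulator protein, was matched at 11.6% against 0.123% (odds ratio 107). NFE2, an erythroid and megakaryocytic leucine zipper factor, had 2.57% against 0.191% (odds ratio 13.8, adjusted exact p = 2.9e-94), AP1 7.27% against 3.69% (odds ratio 2.05) and RUNX 10.9% against 9.23% (odds ratio 1.21, adjusted exact p = 1.5e-06). The NFE2 sequence contains the AP1 sequence, so every NFE2 match is also counted in the AP1 share, and the 2 excesses are not separate. Every match of the GATA pair is likewise counted in the GATA share. The p values of the GATA pair and of CTCF were below the smallest value the computation holds. Fisher's exact test called 11 motifs more frequent at distal summits and 0 less frequent. ETS, NRF1, NFY and PU.1 were among the 11, PU.1 with an odds ratio of 1.18 and an adjusted exact p of 0.024. The sites of CEBP (odds ratio 1.06, adjusted exact p = 0.869), a myeloid factor, EBF (1.16, adjusted exact p = 0.373), a B cell factor, and STAT5 (0.894, adjusted exact p = 0.154) did not differ. HNF1, a liver factor, had 0 matches in both sets, and RFX had 2 at summits and 0 in flanks.

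Promoter summits had another profile. Of 12354 promoter summits, KLF was matched at 39.6% against 7.87% of 20547 flanking windows (odds ratio 7.69) and NFY, which binds CCAAT boxes, at 20.6% against 5.61% (odds ratio 4.36). The odds ratio was 75.5 for NRF1, a factor of CpG-rich promoters (1.45% against 0.0195%, adjusted exact p = 6.0e-70), 22.9 for ETS (adjusted exact p = 3.6e-76), 22.2 for CTCF (adjusted exact p = 2.2e-98) and 5.17 for NFE2 (adjusted exact p = 1.6e-12). The GATA pair was matched at 3.25% against 1.91% (odds ratio 1.72, adjusted exact p = 1.1e-13). GATA alone was less frequent at promoter summits than in flanks, at 16.7% against 29.2% (odds ratio 0.487, adjusted exact p = 1.4e-147), as was STAT5 (odds ratio 0.790, adjusted exact p = 0.0013). Both turned to a higher frequency against the summit windows' own sequence shuffled with dinucleotides kept, with odds ratios of 1.61 for GATA and 2.81 for STAT5. Distal PU.1 was no longer called in 5 of the 8 alternatives.

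Within the series list, the strongest decile of distal regions matched GATA, the GATA pair and KLF most often. GATA was matched at 60.1% (exact 95% interval 57.3 to 62.9) of summits in the strongest decile, at 42.6% (39.8 to 45.5) in the sixth decile and at 46.6% (43.8 to 49.5) in the weakest. The GATA pair went from 27.3% (24.8 to 29.9) in the strongest decile to 9.73% (8.11 to 11.5) in the weakest, and KLF from 25.4% to 15.6% in the sixth and 20.03% in the weakest. In each replicate's own list GATA was most frequent in the second decile, at 64.9% against 59.8% in the strongest for replicate 1 and at 65.7% against 60.7% for replicate 2, and so was the GATA pair, at 30.6% against 27.3% and 29.8% against 28.6%. The 100 strongest distal regions alone had a GATA match in 40% of cases (30.3 to 50.3). CTCF was most frequent in the seventh decile, at 17.4% (15.3 to 19.6), and was matched at 5.32% (4.12 to 6.74) in the strongest and 5.40% (4.19 to 6.84) in the weakest.

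**Figure D3:**
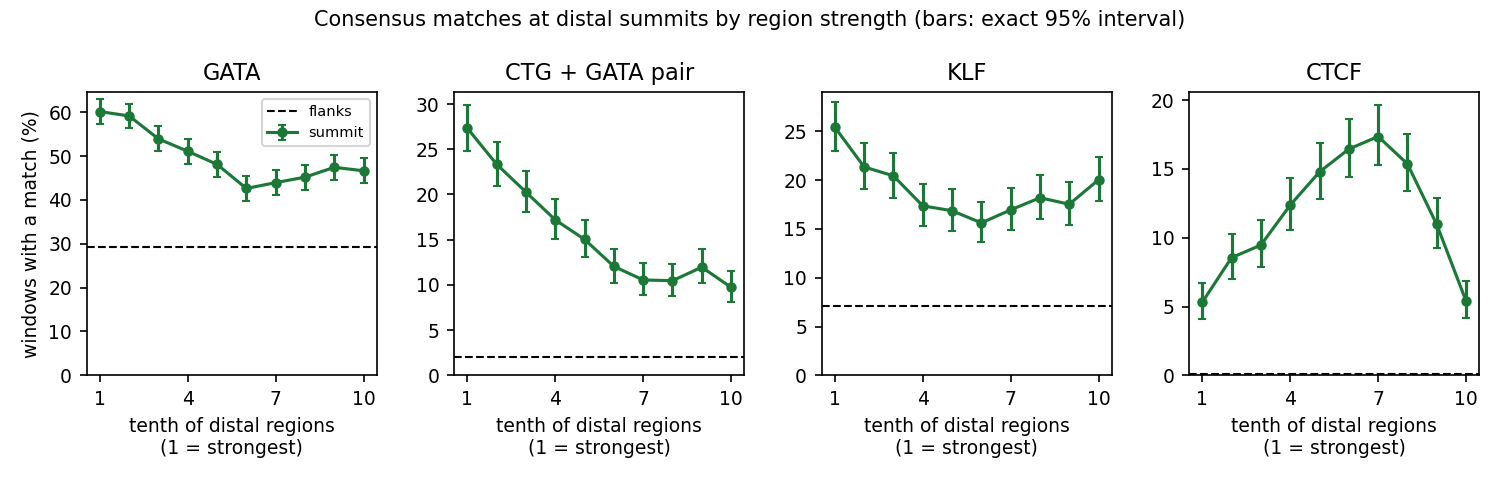
Share of distal summit windows with a GATA, paired CTG and GATA, KLF or CTCF match (%) by decile of region strength within the series list, from strongest to weakest, with exact 95% intervals and the share in flanking windows as a dashed line. GATA falls from 60.1% to 46.6% and the pair from 27.3% to 9.73%, while CTCF peaks at 17.4% in the seventh decile.

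Promoters took 50.6% of regions (95% interval 50.02 to 51.3), against 6.05% of the assembled genome, a ratio of 8.37. Introns held 26.5% of regions (genome 38.3%), intergenic sequence 19.3% (genome 52.4%) and exons 3.599% (genome 3.18%). With each merged region given the fold of its strongest record, promoter regions had a median fold of 9.23, intronic regions 6.37 and intergenic regions 6.77. The share at promoters was 58.2% in replicate 1 and 59.6% in replicate 2, whose lists are shorter. Among autosomes, chromosome 11 had the most regions per Mb, 18.3, and chromosome 14 the fewest, 6.74, with a median of 9.84. The X chromosome had 3.66 regions per Mb, 0.372 (95% Poisson interval 0.343 to 0.404) of the autosomal median, while its density of protein-coding genes was 0.722 of the autosomal median. The Y chromosome had 16 regions, or 0.182 per Mb. The animals were labelled male.

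The strongest distal region lay 12.99 kb from Abcb11, which encodes the bile salt export pump of the liver (chr2:69355472-69355731, intergenic, fold 45.5). The next were chrX:143482940-143483174 (fold 36.0, 35.5 kb from Pak3), chr5:60042656-60043143 (fold 31.4, 1766 kb from G6pd2), chr6:9889882-9890222 (fold 28.6, 940 kb from Nxph1) and chr10:96077465-96077947 (fold 27.6, 58.9 kb from Gm5426). Folds between 27.5 and 24.98 were recorded at chr4:42860555-42861022 (4.02 kb from Gm12394), chr12:97061377-97061851 (1155 kb from Galc), chrX:76598514-76599189 (4.07 kb from Cldn34d), chr16:18533134-18533390 (15.5 kb from Gnb1l) and chr2:3964430-3964681 (53.2 kb from Frmd4a). The highest promoter fold was 27.1. Of the 20 strongest distal regions, 4 lay more than 100 kb from a protein-coding start, and 15 matched the mitochondrial genome or another nuclear copy of their sequence.

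The comparison between samples that the design holds is of replicate 1 with replicate 2. Of replicate 1's regions, 86.5% (95% interval 86.0 to 87.0) overlapped a region of replicate 2, and of replicate 2's, 92.0% (91.5 to 92.3) overlapped a region of replicate 1. Random placements gave 0.957% and 1.04% on average. The Jaccard index of bases was 0.752. Regions of the strongest decile were shared at 99.6% in both replicates, and those of the weakest at 62.0% (59.8 to 64.3) in replicate 1 and 74.1% (72.0 to 76.1) in replicate 2. The log2 ratio of −log10 p between the libraries had an SD of 0.31 over 7291 regions, against 0.43 between random splits of the pooled reads, whose median −log10 p was 0.992 of that of the libraries. The ratio of variances was 0.521 (bootstrap interval 0.502 to 0.544) and lay below 1 on 20 of 20 chromosomes. Replicate 1 had 1.09 times as many records as replicate 2, and the pooled pseudoreplicates gave 0.9997 times as many as the true replicates. The IDR threshold kept 69.3% of the records in the overlap list made from pseudoreplicates.

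**Figure D4:**
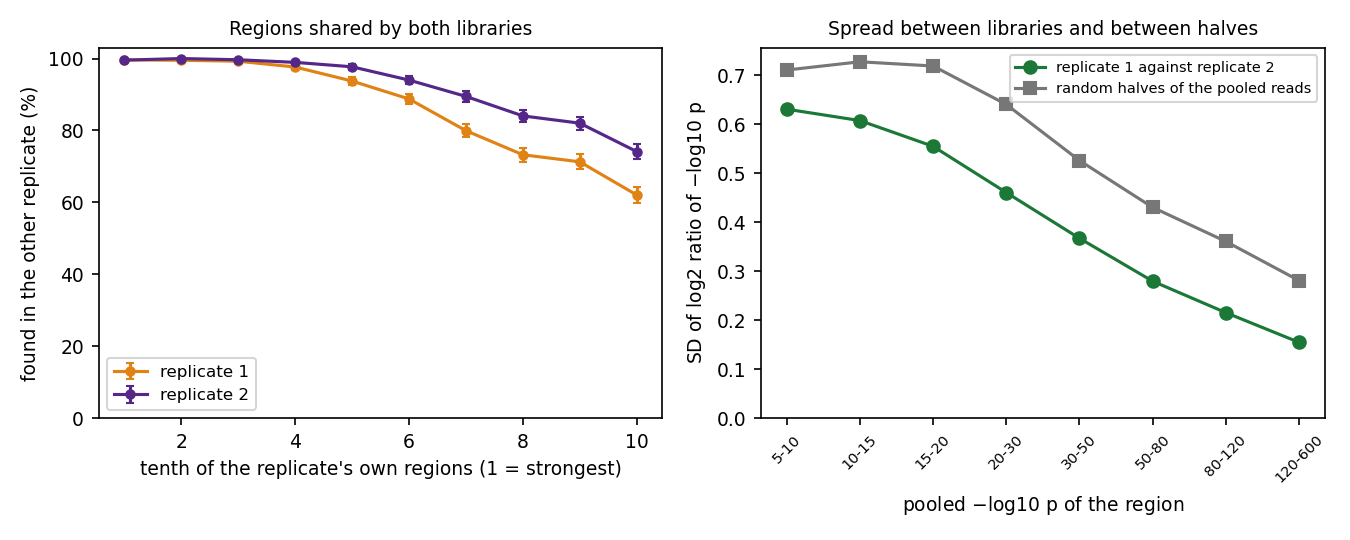
Left, share of each replicate's regions found in the other (%) by decile of the replicate's own regions, from strongest to weakest, with exact 95% intervals. Right, SD of the log2 ratio of −log10 p by pooled −log10 p, between the libraries and between random splits of the pooled reads, with the libraries lower in every bin.

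Regions found in 1 replicate only were more often distal than shared regions, and their distal summits matched GATA less often. Replicate 1 had 337 regions without any counterpart in replicate 2's less strict list (1.80%), and 36.2% of them were promoter regions, against 58.6% of its shared regions (odds ratio 0.401, Fisher's exact p = 3.4e-16). Replicate 2 had 145 (0.812%), of which 33.1% were promoter regions against 59.8% (odds ratio 0.332, Fisher's exact p = 1.2e-10). At distal summits, GATA was matched at 40.9% against 55.6% in replicate 1 (adjusted exact p = 0.00022) and at 33.0% against 55.8% in replicate 2 (adjusted exact p = 6.1e-05), and the GATA pair at 6.51% against 19.96% and 2.06% against 20.4%. CTCF was matched at 14.9% against 8.57% in replicate 1 (adjusted exact p = 0.016) and at 14.4% against 8.21% in replicate 2, where it missed the threshold (adjusted exact p = 0.155). The regions found in 1 replicate only had a median fold of 4.88 in replicate 1 and 4.45 in replicate 2, against 8.45 and 8.39 for shared regions. The comparisons were not matched on fold, so a difference in kind cannot be told apart from the lower strength of these regions.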

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

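All tests in this part, matching on CpG content among them, were chosen after the patterns were seen. The tests of shared reads and of unequal depth, and the matching of single gene lists on CpG content, were also chosen only after the result was seen, and for the others the expected value was written down before the test was run. The labels name no further group of samples, so no biological explanation was tested for any of the patterns except a class of erythroid elements with GATA sites for the strongest distal regions.

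The 2 libraries differed less than random splits of their pooled reads did, with a variance ratio of 0.521 where every region had 1 record, which argues against the pairing of records at regions with several summits. The median −log10 p of the splits was 0.992 of that of the libraries, which argues against unequal depth, although read numbers were not known. That the split of the pooled reads was random was assumed and not tested. Loss of reads at strong regions when duplicates are removed is argued against as the whole cause, because the ratio was still 0.788 (bootstrap interval 0.749 to 0.833) at the weakest regions, with a −log10 p of 5 to 10, and 0.697 (0.639 to 0.760) at 10 to 15. It stays open as a part, because the ratio fell with strength to 0.303 at the strongest regions. Reads or molecules shared by both libraries also stay open, since a ratio below 1 on 20 of 20 chromosomes, between 0.456 and 0.633, restates the pattern and does not single this explanation out.

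The strongest distal regions were weighed against copies of their sequence. Of the 20 strongest, 5 matched mitochondrial DNA over 100 bp or more at 95.8% to 100% identity, against 0 of 100 random distal regions (Fisher's exact p = 8.1e-05), and 5 was the smallest number set in advance as meaningful. Another nuclear copy existed for 13 of the 20, against 7 of 100 random regions (Fisher's exact p = 4.4e-08), so reads from the mitochondrial genome or from repeated sequence may account for the 15 regions with either kind of match. A class of erythroid elements with GATA sites found no support. Of the 100 strongest distal regions, 40% (exact interval 30.3 to 50.3) had a GATA match. Of the 73 of them without a copy, 42.5% (31.0 to 54.6) had one. Both shares lay below the 49.8% of all distal regions. A share at or below that level was the outcome set in advance against this class. Both intervals reach 49.8%, so the class is not excluded. Of the 20 strongest, 6 had a GATA match. The 5 regions with neither kind of copy stay open, and distance from genes marked only 4 of the 20.

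Promoter regions were rare in the lists of other cell types and frequent in the erythroid lists, and the share of genes with one rose from 4.43% in the decile of lowest promoter CpG content to 82.4% in the highest. Low CpG content is argued against as the whole cause for other cell types, because 13 of their 146 genes had a promoter region against a mean of 33.9 (central 95% 25 to 43) in random sets matched on CpG. High CpG content is argued against in the same way for the erythroid lists, with 100 of 114 genes against a mean of 58.5 (50 to 67). Both permutation p values were 0.0002, the smallest that 10000 sets can give. CpG content may still account for part of the difference, since the share of genes with a promoter region rose with it. Matching on it ended the call of 6 single lists. For the macrophage, mast cell and hepatocyte lists among them, the central 95% of matched counts reached 0. No deficit could be called there, so their lost calls say nothing about CpG content.

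An older list of replicated peaks, outside the comparisons above, held 140866 regions absent from the overlap list of the series, 74.0% of its 190299. Their median fold was 3.04 against 5.40 for the regions present in both, and 13.4% against 42.02% were promoter regions. The ranked list held 102 records past the IDR threshold on 13 sequences outside the chromosomes that the thresholded list leaves out, with a highest fold of 18.6. It also held 167 such records on the chromosomes, in 86 regions, the strongest of which was at chr3:5860552-5860882 with a fold of 33.9.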

How the results depend on the processing

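The matching on promoter CpG content and the runs of peak numbers and of motifs by rank on single replicates were chosen only after the result was seen. No paired analysis was possible because there is only 1 group. Where a value moved, the cause was not tested, except that unmerged, less strict and stronger lists change the number of regions by construction. The number of regions was 50003 as unmerged records, 42936 with the overlap list and 12197 in the upper 50% by fold. Replicate 1 shared 82.6% and replicate 2 shared 86.5% of its regions at an overlap of at least 50%, 80.3% and 86.3% with the overlap lists, 88.8% and 93.1% in the upper 50% by fold, and 98.2% and 99.2% against the other's overlap list. In the weakest decile the shares at 50% overlap were 56.5% and 62.9%. The share of promoter regions was 44.3% with windows of 500 bp, 60.1% with 2.5 kb, 38.9% with the overlap list, 64.6% in the upper 50% by fold and 58.2% to 59.6% in single replicates. The X to autosome ratio was 0.313 with the overlap list.

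Gene lists with more accessible promoters numbered 4 in the upper 50% by fold and 0 against genes with a region in their domain; lists with fewer numbered 2 against that background and 3 when matched on CpG. That background selects genes for having a region and 83.7% of it had a promoter region, which left little room above: the 7 lists called above other genes otherwise kept shares of 90.9% to 100%. In the upper 50% by fold the erythroid regulators turned to 28.6%, the globins to 0% and erythropoietin signalling to 26.7%, all below other genes, the last called in neither run. Other turns of lists called in neither run were the globins on replicate 1's list alone (40%, below other genes), erythropoietin signalling against genes with a region in their domain (75%) and matched on CpG (60%, both below), and the megakaryocyte list matched on CpG (31.3%, above). Erythropoietin signalling rose above other genes with the overlap list (14 of 15 genes, 93.3%, adjusted exact p = 0.0018), and the globins rose above genes matched on CpG (adjusted permutation p = 0.0023). The clustering of the globin genes was not taken into account there. Lists with more distal regions numbered 2 with the overlap list and 1 in the upper 50% by fold. No list whose distal median lay off that of matched lists turned direction in the distal alternatives. Matched medians were 0 except for the endothelial list with the overlap list, and counts cannot be negative. A list above them could therefore turn only in the run by the mean, and the lack of turns elsewhere was given by construction. On replicate 2's list alone the iron (adjusted permutation p = 0.046) and organelle clearance (0.032) lists came to exceed matched lists, as did organelle clearance on replicate 1's (0.046) and the ribosomal list with the conservative list (median 0.5, 0.0091). The megakaryocyte list also had a median of 0.5 there (adjusted permutation p = 0.078).

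Distal motifs less frequent at summits numbered 1 with the overlap list, 1 with windows of 50 bp and 2 with shuffled controls. At promoters, shuffled controls gave 11 more frequent and 0 less frequent motifs, and windows of 50 bp gave 1 less frequent. Shuffled controls turned the odds ratios of distal CEBP (0.438), NFY (0.797) and STAT5 (1.79) and of promoter GATA (1.61), AP1 (1.63), STAT5 (2.81), RUNX (1.0997) and EBF (0.880), the last 2 uncalled. Motifs called in neither run also turned: distal CEBP with the overlap list (0.944) and in the upper 50% by fold (0.689), distal EBF in the upper 50% (0.976), with windows of 50 bp (0.971) and in single replicates (0.963 to 0.984), distal STAT5 (1.06) and promoter CEBP (1.24) with controls at 5 kb, and promoter AP1 (1.01) and RUNX (1.002) with the overlap list and AP1 with windows of 50 bp (1.19). Promoter STAT5 lost its call with controls at 5 kb (0.945, adjusted exact p = 0.457) and windows of 50 bp (0.821, 0.077). AP1 (0.837, adjusted exact p = 0.0079) and RUNX (0.874, 0.0012) became less frequent at promoters with controls at 5 kb, and AP1 in the upper 50% by fold (0.810, 0.026). Distal STAT5 became less frequent with the overlap list (0.874) and windows of 50 bp (0.737). Distal EBF became more frequent with the overlap list (1.36), controls at 5 kb (1.49) and shuffled controls (1.47), and promoter PU.1 in the upper 50% by fold (1.21), with controls at 5 kb (1.16) and with shuffled controls (2.15). The call of distal PU.1 was lost on each replicate's list alone (adjusted exact p = 0.063 and 0.463). GATA in the strongest decile was 50.2% with windows of 50 bp, and CTCF there was 3.74% to 4.10% in single replicates. Of the results for single lists and motifs, 458 kept their side of the threshold without turning direction, 43 lost a call, 19 gained one and 26 turned direction. The unknown read depth limits what the absence of a region at a gene can show.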

Other observations

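Distal regions nearest to genes of the 7 erythroid lists differed in motif content from other distal regions. Of these 320 regions, 62.2% had a GATA match and 26.6% a KLF match, against 49.5% and 18.8% of the other 11719 (adjusted exact p = 5.6e-05 and 0.0045). STAT5, the factor activated by the erythropoietin receptor, was matched at 5.00% against 2.45% (odds ratio 2.10, adjusted exact p = 0.038), although it did not differ between all distal summits and their flanks. CTCF was matched at 4.06% against 11.8% (odds ratio 0.316, adjusted exact p = 3.5e-05). The GATA pair, at 20.3% against 15.7%, missed the threshold after adjustment over the 16 motifs (adjusted exact p = 0.094). These tests treat the 320 regions as independent, although many share a gene's domain, as 15 do at Zfpm1 and 13 at Sox6. Nor were the regions matched on fold, with which the share of GATA matches varied.

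The first hypothesis, written before its test, was that GATA matches are more frequent in distal regions nearest to erythroid genes. The odds ratio was 1.68 (Fisher's exact p = 7.0e-06), which is in the direction of this hypothesis in this sample. The limits on independence and fold given above hold for it. The other hypothesis, also written before its test, was that CTG and GATA sites occur at a preferred spacing. The main motif comparison had pooled spacings of 7, 8 and 9 bases in the same summits and flanks, with an odds ratio of 9.03. A highest value within that range was therefore largely given by that result and is not independent support. The pooled count did not separate 7, 8 and 9 bases, so the order among them was new. Among spacings of 4 to 14 bases, the odds ratio of distal summits over flanks was highest at 8 bases, at 13.9 (95% interval 11.6 to 16.5), followed by 7.63 at 7 bases and 4.68 at 9 bases, against a median of 3.32 over the spacings. These shares may reflect binding by complexes of TAL1 and GATA1 at a spacing of 8 bases, but no binding was measured here.

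Among the lists of other lineages, the megakaryocyte and platelet list had 17 distal regions over 16 genes, 7 of them at Vwf, and the stem and progenitor list had 13 over 23 genes, 7 of them at Runx1. The T and NK cell list had 11 over 22 genes, 6 of them at the NK receptor gene Klrb1c. The mast cell list had 5, the neuron and macrophage lists 4 each, the granulocyte and hepatocyte lists 3 each, the endothelial list 2 and the B cell list 0. By the mean in place of the median, the organelle clearance list (2.00 distal regions per gene, adjusted permutation p = 0.0092) and the ribosomal list (0.850, adjusted permutation p = 0.049) exceeded matched lists, and the B cell list did not differ (adjusted permutation p = 0.136).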
